A study of Mus musculus with 2 samples.

How the data were processed

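Total RNA from 2 mouse mesoangioblast clones, D16 and D351, was measured on 1 oligonucleotide array each, the C array of the Affymetrix murine U74 set, per the labels. Mesoangioblasts are vessel-associated mesodermal progenitor cells that grow out of the embryonic dorsal aorta. The deposited table held 1 linear intensity for each of 11934 probe sets on each array, the value into which the authors had summarised a group of probes. The software and settings that made these intensities are not given in the sources used here, and no detection calls were used here. The mean over probe sets with the lowest and highest 2% left out was 20.01 on both arrays, as scaling to a common mean would give, and the intensities were used as deposited. No value lay below 0, and 4 values of D351 were exactly 0.

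The 66 control probe sets of the manufacturer were set aside, which left 11868. The median of all remaining values of both arrays, 6.4, served as a floor. A value at or below the floor was called dim, and a probe set was called measured when it was above the floor in at least 1 clone. Dim values were raised to the floor before log2 was taken. Every log2 ratio is D351 minus D16, and a probe set dim in 1 clone gives a lower bound, written as "at least". As a guide to background, 19 control probe sets for bacterial and yeast transcripts that were not hybridization controls had a median of 1.9 over 38 values, and 8 of these values were above the floor.

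Gene names came from the platform annotation. Of the 11868 probe sets, 7717 had a single gene, 150 had several and 4001 were unnamed here. Of the 7717 gene identifiers, 7677 were found in the RefSeq gene table of assembly GRCm38.p6, and 0 symbols changed. That table also gave the chromosome of each gene. A gene was represented by its brightest probe set, the one with the highest mean floored log2 value, which gave 5928 genes, of which 3934 were measured. Probe sets with several genes or none entered the counts of probe sets only.

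With 1 array per clone there was no replicate and no test, and the number of arrays limits the precision. Differences were described by a fixed rule of size, 2-fold. The genes named in the text followed a rule. For each clone it took the 12 genes with the largest ratio among those above the floor in both clones and the 6 with the largest lower bound. Locus names were passed over, as were genes with a second measured probe set of opposite sign beyond 0.5 log2, which removed 1 and 2 genes. From each gene list it took up to 4 members past 2-fold in each direction, or the 2 brightest members where none was. The control probe sets were named as well. The 37 gene lists concern cell types that the cultures could hold, signalling pathways, growth, metabolism and gene families. The C array held only part of the cell type lists, with 31 smooth muscle, 11 embryonic fibroblast and 17 skeletal muscle genes. Such a list therefore does not cover its whole cell type. The median log2 ratio of each list with at least 3 measured genes was placed among the medians of 10000 random lists of the same size, drawn from the measured genes in 10 bins of matching mean intensity (seed 1). A list is said to stand apart when its median lay below the 2.5 or above the 97.5 percentile, which describes these 2 arrays and is not a test. Chromosomes were treated as lists in the same way.

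The gene lists, the floor, the 2-fold rule, the naming rule and most alternatives were fixed before the data were examined. These alternatives were quantile normalization, lowess centring (span 0.3) of log2 ratios on mean log2 intensity, and equal medians of the probe sets measured in both clones. Others were a floor at the 25th or 75th percentile, a pseudocount of the pooled median in place of the floor, and a 3-fold rule. The last were probe sets without a mark in their identifier, and the mean over a gene's measured probe sets. A mark (f, g, i, r, s or x) denotes relaxed probe selection or sequence shared between transcripts. Scaling to the hybridization controls, and lists without shared members, were added after the data had been seen.

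The procedure was tested on simulated arrays with the real intensities. The probe sets to be changed were drawn only from those bright in D16. Of 100 changed 4-fold, 99.0% were called in the right direction, and of 100 changed 8-fold, 100%. Of 6040 unchanged measured probe sets, 1.51% passed 2-fold with the simulated noise, on arrays of 11868 probe sets. That noise was smaller than the spread of log2 ratios between real probe sets of the same gene (SD 0.68). These rates therefore do not carry over to dim probe sets or to the real arrays. Of 200 random lists of 30 genes without a shift, 12 stood apart, and of 200 lists shifted by 0.5 log2 all 200 did, over 3640 genes. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.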

Results

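Clones D16 and D351 were derived from the dorsal aorta of C57BL6 mouse embryos at embryonic day 9.5. Explanted cells were cloned by limiting dilution on growth-arrested embryonic fibroblasts, and the clones were then expanded on gelatin. The labels place the study in smooth muscle differentiation and vascular stem cells, and the series title sets the clones against each other. Each clone contributed 1 array, so no difference below has a replicate check. The median intensity was 6.5 in D16 and 6.2 in D351, and 5956 and 5832 probe sets were above the floor.

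The 2 arrays were alike for most transcripts but differed strongly in a minority, part of which measurement error can give, as set out below. D351 carried far more RNA of the smooth muscle protein leiomodin 1 (Lmod1), of Sox11, of Itga8 and of 2 non-coding RNAs, Hoxb5os and Mirg. D16 carried far more of the transcription factor Tfap2a, of cyclin D1 (Ccnd1), of Gas7 and of Xaf1. Hoxb5os, Mirg and Gas7 were measured only by probe sets with a mark in their identifier. Of 173 named genes past 2-fold, 107 had a measured probe set without a mark, and 103 of these passed 2-fold by it. As groups, matrix and fibroblast genes were higher in D351, although the matrix median was -0.11 over the 13 members with a measured probe set without a mark. Genes of the cell cycle were higher in D16, with a median of -0.54. Scaled to the hybridization controls it came to -0.0061, still at percentile 0 of the matched random lists, whose middle value was then 0.61. Of 6828 measured probe sets, 665 were at least 2-fold higher in D351 and 666 in D16, together 19.5%. In D351, 411 of the 665 were ratios between measured values and 254 were lower bounds, and in D16 the numbers were 432 and 234. Over 4960 probe sets measured in both clones, the log2 ratios had a median of -0.013 and an SD of 0.83. The log2 intensities correlated across these probe sets with a Pearson r of 0.858 and a Spearman rho of 0.814, and genes are not independent replicates. By gene, 404 were at least 2-fold higher in D351 and 403 in D16.

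Probe sets of the same gene also differed. For 409 genes with more than 1 probe set measured in both clones, the log2 ratios of the brightest pair had an SD of 0.68 per probe set around each other and correlated with r = 0.383. This SD is not far below the 0.83 between the clones, so measurement error can give part of the 2-fold calls. How large a part cannot be said without replicate arrays. Among 128 genes past 2-fold with a second measured probe set, the second lay in the same direction for 85 (66.4%). It was itself past 2-fold for 34, and past 2-fold in the opposite direction for 8. The 9 probe sets of the hybridization controls BioB, BioC, BioD and CreX were a median of 1.59-fold brighter in D16 (log2 ratio -0.67, range -0.83 to -0.60). Directions are therefore relative to the mean of all probe sets. Why these controls were brighter in D16 was not tested, so scaling to them need not give true RNA levels. Scaling to these controls adds 0.67 to the log2 ratio of a probe set that is above the floor in both clones before and after. With dim values raised to the floor, it moved the medians of 36 gene lists by -0.0077 to 0.76, with a middle value of 0.64. It would also turn the even split of 2-fold probe sets, 49.96% higher in D351, into 1836 against 241, or 88.4%. The ratio of 3' to 5' control probe sets was 1.39 in D16 and 1.22 in D351 for Gapdh, and 1.49 and 1.24 for Actb. The negative controls reached 11.2, above the floor of 6.4, so folds over values this low depend on the floor. Of 115 genes taken by the naming rule with a ratio past 2-fold between measured values, 36 had a lower value within that range. With the floor at the 75th percentile, 20.7, 18 of the 36 passed 2-fold, 13 did not and 5 were dim in both clones; of the other 79, all but Col11a2, Pfkfb2 and Prdx4 still passed. Of 58 lower bounds past 2-fold taken by that rule, 21 still passed, 15 did not and 22 were dim in both; those that no longer passed were the bounds under 6.47-fold.

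**Figure D1:**
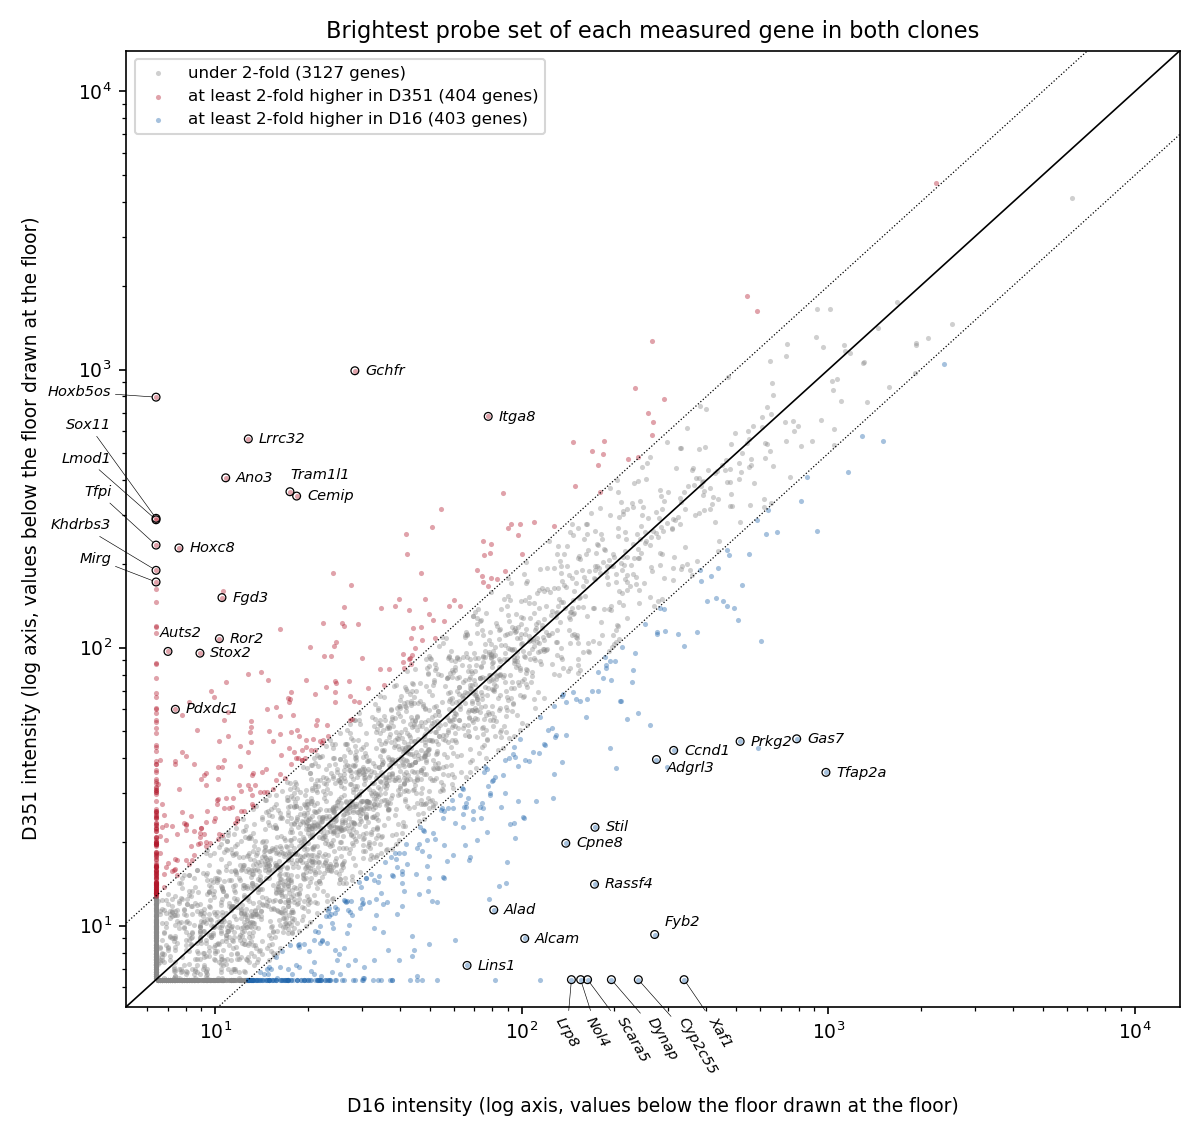
Intensity of each gene's brightest probe set in D16 (x axis) and D351 (y axis), both on log axes with dim values at the floor of 6.4. Points are 3934 measured genes and dotted lines mark 2-fold, with 404 genes at least 2-fold higher in D351 and 403 in D16. For each clone, names mark the 12 largest ratios and the 6 largest lower bounds taken by the naming rule.

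Among genes measured in both clones, Lrrc32 had the largest ratio towards D351 with the floor at 6.4, although with the floor at 20.7 it was at least 27.2-fold higher and Gchfr 34.7-fold. Lrrc32, whose product holds latent TGF-beta at the cell surface, had an intensity of 12.8 in D16 and 563 in D351, a 44.0-fold difference. Ano3, of the anoctamin membrane proteins, was 37.8-fold higher, and at least 19.7-fold with the higher floor. Gchfr regulates tetrahydrobiopterin synthesis. The homeobox gene Hoxc8 stood at 7.6 in D16 and 228 in D351. Tram1l1 was 20.8-fold higher, and its other probe set also lay towards D351, at 7.4 in D16 and 64 in D351. Cemip, which takes part in hyaluronan breakdown, was 19.1-fold higher, and Fgd3, an exchange factor for small GTPases, 14.4-fold. Auts2 (13.8-fold), Stox2 (10.7-fold), the Wnt5a receptor Ror2 (10.5-fold), the integrin chain Itga8 (8.74-fold) and Pdxdc1 (8.11-fold) completed the set. In 7 of these 12 genes (Ano3, Hoxc8, Fgd3, Auts2, Stox2, Ror2 and Pdxdc1) the D16 value lay within the range of the negative controls. With the floor at 20.7, Fgd3 was at least 7.31-fold, Hoxc8 at least 11-fold, Auts2 at least 4.68-fold, Stox2 at least 4.61-fold, Ror2 at least 5.20-fold and Pdxdc1 at least 2.90-fold higher in D351. Of genes dim in D16, Hoxb5os, an antisense transcript of the Hoxb cluster, reached 795 in D351, at least 124-fold higher. Sox11 was at least 45.6-fold higher, and Lmod1, dim in D16, reached 288 in D351. Tfpi, the tissue factor pathway inhibitor, was at least 36.5-fold higher, the RNA-binding Khdrbs3 at least 29.6-fold and Mirg at least 26.9-fold. With the floor at 20.7 the bounds of these 6 were lower, from 38.4-fold for Hoxb5os and 14.1-fold for Sox11 down to 8.32-fold for Mirg. Gchfr, Ror2, Hoxb5os and Mirg were measured only by probe sets with a mark.

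Of the genes higher in D16, Fyb2 had an intensity of 271 in D16 and 9.3 in D351, 29.1-fold higher in D16. Tfap2a, a transcription factor of neural crest and surface ectoderm, stood at 981 in D16 and 35.6 in D351, 27.6-fold higher in D16. Gas7 was 16.8-fold higher in D16. Its other probe set had a log2 ratio of -4.53, but it was built on the same sequence and is not an independent reading. Rassf4 was 12.2-fold higher in D16, the adhesion molecule Alcam 11.3-fold and the cGMP-dependent kinase Prkg2 11.2-fold. Ccnd1, the D-type cyclin of G1 phase, had an intensity of 313 in D16 and 42.7 in D351, a 7.32-fold difference. Stil, needed for centriole assembly, was 7.66-fold higher in D16, Lins1 9.19-fold, the haem synthesis enzyme Alad 7.10-fold, Cpne8 7.02-fold and Adgrl3 6.94-fold. In 3 of these 12 (Fyb2, Alcam and Lins1) the D351 value lay within the range of the negative controls, and with the floor at 20.7 they were at least 13.1-fold, 4.93-fold and 3.20-fold higher in D16; Alad, at 11.4 in D351, was at least 3.91-fold higher. Of genes dim in D351, Xaf1 was at least 52.8-fold higher in D16 and Cyp2c55 at least 37.5-fold. Dynap was at least 30.6-fold higher by its brightest probe set, but another, near background, read 11.9 in D16 and 10 in D351. Scara5, a ferritin receptor, was at least 25.6-fold higher, Nol4 at least 24.3-fold and the reelin receptor Lrp8 at least 22.7-fold. With the floor at 20.7 the bounds of these 6 ran from 16.3-fold for Xaf1 down to 7.0-fold for Lrp8. Only probe sets with a mark measured Fyb2, Gas7, Alcam, Stil, Alad, Cpne8, Cyp2c55, Dynap and Nol4.

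Extracellular matrix genes were higher in D351 as a group. Of 32 measured members, 14 were at least 2-fold higher in D351 and 1 in D16, with a median log2 ratio of 0.66, and 0 of 10000 matched random lists reached it. Smoc2, a matricellular protein, was at least 8.58-fold higher, and at least 2.65-fold with the floor at 20.7. Mfap5, a component of elastic microfibrils, was 6.14-fold higher at 257 in D351. Egfl6 (8.7 in D16 and 50.5 in D351) and, by its brightest probe set, Col6a4 (9.7 and 69.6) were at least 2.44-fold and 3.36-fold higher with the floor at 20.7, but another probe set of Col6a4 read 11.5 in D16 and was dim in D351. The exception was the protease Adamts10, at least 3.08-fold higher in D16. Only 13 members had a measured probe set without a mark; over these, 5 were higher in D351 and 0 in D16, the median was -0.11 and the list no longer stood apart. By their brightest probe sets the same 13 had a median of 0.23, against 0.70 for the other 19. The markers of embryonic fibroblasts, the cell type of the feeder layer, moved with the matrix genes. All 8 measured were above 0 and 5 passed 2-fold, with a median of 1.57 at percentile 99.99. They included Mfap5, the growth factor Fgf10 (4.76-fold higher), Col5a1 (3.38-fold, 543 in D16 and 1838 in D351) and the cross-linking enzyme Loxl1 (3.19-fold). Another probe set of Fgf10 read 17.9 in D16 and 28.6 in D351, under 2-fold. Of the 8 markers, 6 were also on the matrix list.

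Smooth muscle genes, the fate named in the labels, leaned to D351. Of 24 measured, 6 were at least 2-fold higher in D351 and 3 in D16, with 13 above 0 and 11 below, and the median of 0.28 lay at percentile 97.55. Scaled to the hybridization controls, 9 of 23 were higher in D351 and 0 in D16, but the list no longer stood apart (percentile 96.5). Beside Lmod1 and Itga8, Synpo2 was 4.26-fold higher in D351, with its second probe set at 1.31 log2. Ppp1r12a, the myosin phosphatase targeting subunit, was 2.47-fold higher. Towards D16 lay the actin cross-linker Flnc, 2.27-fold higher and bright in both clones (2385 and 1048), Rbpms (16.2 and 7.1) and Tagln2 (2.16-fold). The list no longer stood apart under 4 of 8 alternative settings. Of 5 measured mural cell and pericyte markers, Bgn (2.09-fold) and Rgs4 (6.8 in D16 and 13.8 in D351) were higher in D351 and Angpt1 at least 4.09-fold higher in D16. Their median was 0.63 and their mean -0.00065. Among 6 cardiac genes, Kcnj2 (7.2 in D16 and 22.8 in D351) and Tbx5 (10.1 and 28.3) passed 2-fold towards D351, but not with the floor at 20.7. The list had a median of 0.51 at percentile 95.2, and the list stood apart under 2 of the 8 settings. Of 7 skeletal muscle genes only Pvalb passed 2-fold (2.82-fold higher in D351), and the median was -0.20 with a mean of 0.068.

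Genes of the cell cycle and DNA replication were higher in D16. Of 58 measured, 21 were at least 2-fold higher in D16 and 2 in D351, with 48 below 0. Their median log2 ratio was -0.54, and 0 of 10000 random lists lay as low; with both arrays scaled to the hybridization controls it was -0.0061, still at percentile 0, and 7 genes were at least 2-fold higher in D16 and 4 in D351. Named members were Stil, the DNA polymerase delta subunit Pold1 (4.40-fold higher in D16), the dUTPase gene Dut (49.9 in D16 and 8.6 in D351) and the centromere protein gene Cenpn (44.4 and 8.2). With the floor at 20.7, Dut was at least 2.41-fold and Cenpn at least 2.14-fold higher in D16. Against this direction, Ube2s stood at 8.3 in D16 and 24.9 in D351. Zwint was at least 2.45-fold higher in D351 by 1 probe set, while another read 14.6 in D16 and was dim in D351. Of 8 genes for cell cycle inhibition and p53 targets, Mdm2, the ubiquitin ligase of p53, was 3.68-fold higher in D351 (233 and 857), and Mdm4 stood at 9.9 in D16 and 23.8 in D351. The p53 targets Zmat3 and Tigar were 3.34-fold and 3.32-fold higher in D16, and the median of 0.48 did not stand apart.

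**Figure D2:**
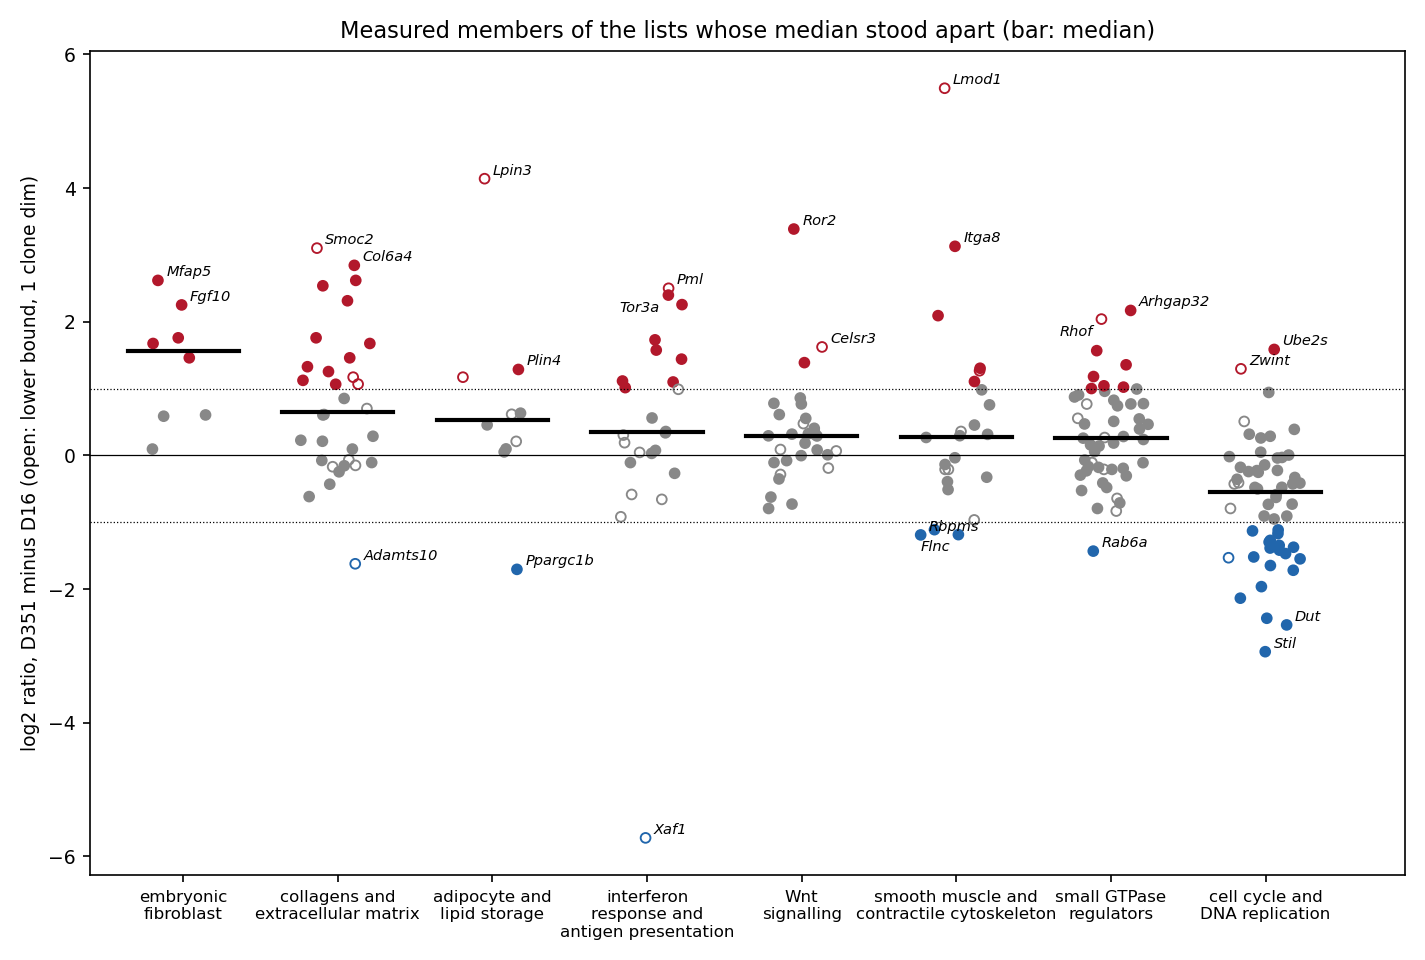
log2 ratio, D351 minus D16 (y axis), of each measured member of the 8 lists that stood apart (x axis), with bars at the medians, open circles for lower bounds and dotted lines at 2-fold. Medians run from 1.57 for fibroblast markers to -0.54 for the cell cycle. Scaled to the hybridization controls the cell cycle median was -0.0061, against 0.61 for matched random lists.

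Another 4 lists stood apart towards D351. Interferon response and antigen presentation had 9 of 24 genes higher in D351, 1 in D16 and a median of 0.35 (percentile 98.3). Over the 17 genes with a measured unmarked probe set the median was 0.19 (percentile 83.3), and the list no longer stood apart. Lgals3bp was 4.77-fold higher (266 and 1268). Pml (dim in D16 and 36.2 in D351), Tor3a (7.4 and 39.0) and Slfn8 (10.2 and 33.8) passed 2-fold too, but not with the floor at 20.7. The exception was Xaf1. In Wnt signalling, 3 of 30 genes passed 2-fold, all towards D351, and the median was 0.29 (percentile 99.1). They were Ror2, Celsr3 (at least 3.08-fold, but dim in both clones with the floor at 20.7) and the receptor Fzd8 (2.62-fold). The list called small GTPase regulators also holds GTPases themselves (Rab2b, Rab6a and Rhof) and Rgs17, a regulator of heterotrimeric G proteins. It does not single out regulators of small GTPases. On this list, 8 of 50 genes were higher in D351 and 1 in D16, with a median of 0.26 (percentile 99.4). Rab2b was 2.56-fold higher in D351. Rhof (dim in D16 and 26.3 in D351) and Rgs17 (7.9 and 23.4) passed 2-fold towards D351, but not with the floor at 20.7, while Rab6a was 2.70-fold higher in D16. Arhgap32 stood at 10.3 in D16 and 46.3 in D351 by its brightest probe set, at least 2.24-fold higher with the floor at 20.7, but another read 26.4 in D16 and 7.8 in D351. The adipocyte list had 3 of 10 genes higher in D351 and 1 in D16 (median 0.54, percentile 97.6). Lpin3 was at least 17.6-fold higher in D351, with a second probe set dim in D16 and at 32 in D351, Plin4 2.44-fold and Plin5 at least 2.25-fold, the last dim in both clones with the floor at 20.7. The coactivator gene Ppargc1b was 3.26-fold higher in D16. Under these settings the Wnt and interferon lists no longer stood apart in 2 of 8 each and the adipocyte list in 3 of 8.

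In all, 8 of 36 lists with a percentile stood apart, where 1.8 would by chance if lists were independent. Several share genes. Scaled to the hybridization controls, the genes at least 2-fold higher in D351 and in D16 became 18 and 1 for the matrix list, 7 and 0 for the fibroblast list, 13 and 1 for interferon, 10 and 0 for Wnt, 22 and 0 for small GTPase regulators and 5 and 1 for the adipocyte list. The sex-linked list had 0 named genes on this array.

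**Figure D3:**
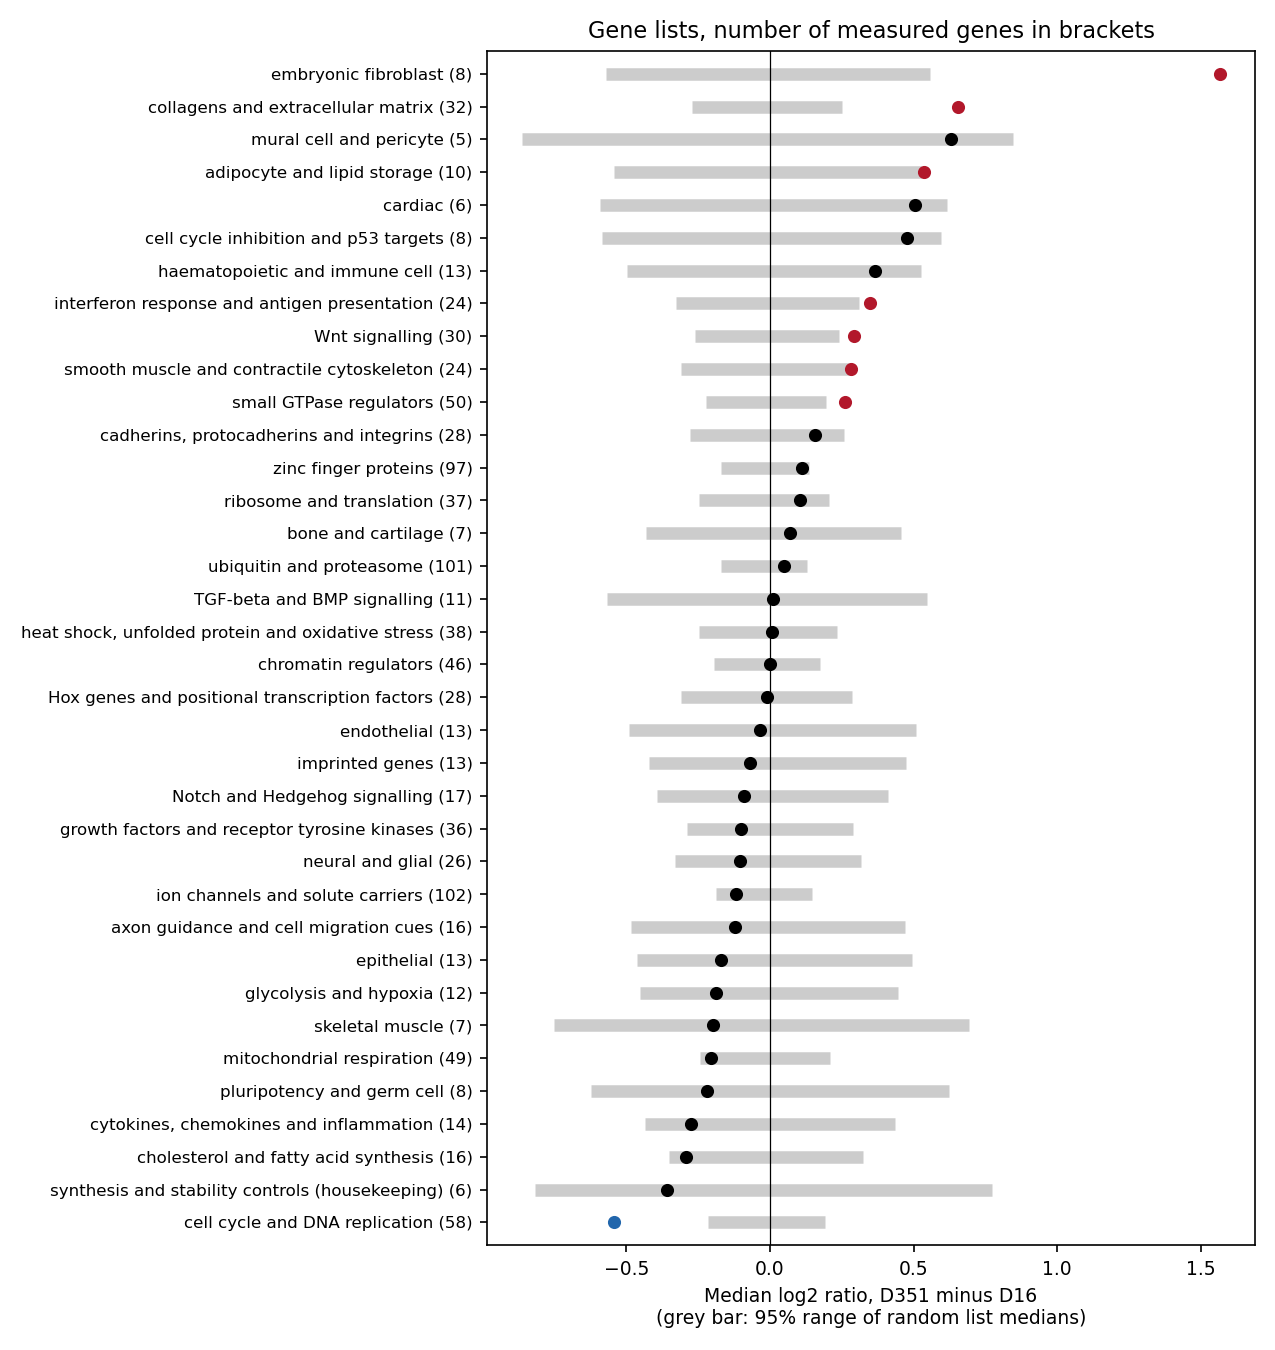
Median log2 ratio, D351 minus D16 (x axis), of 36 gene lists (y axis, measured genes in brackets), with grey bars for the range that holds 95% of the medians of matched random lists. The medians of 7 lists lie above their bars and 1, the cell cycle, lies below. Scaled to the hybridization controls, 35 of the 36 medians were above 0. That of the cell cycle was -0.0061, still at percentile 0 of its matched random lists.

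Markers of other cell types did not stand apart as groups, but single genes differed widely. The array held only part of these markers, with 19 endothelial, 23 haematopoietic and immune and 13 bone and cartilage genes. The medians therefore speak for those genes and not for whole cell types. Of 13 measured genes of the endothelial list, the VEGF receptor gene Flt1 was at least 13.7-fold higher in D351. Sox11 is on this list and on that of Hox and positional genes, and its bound of 5.51 log2 raises the mean. Egfl7 was at least 3.05-fold and Grrp1 2.02-fold higher in D16. The endothelial median was -0.036 and the mean 0.55. None of 13 haematopoietic and immune genes passed 2-fold, with a median of 0.37 and Itga2b at 0.37. Nkg7 had a log2 ratio of 0.54 by its brightest probe set and 0.23 by another, while the remaining one read 11 in D16 and was dim in D351. Among 7 bone and cartilage genes only Col11a2 passed 2-fold (2.38-fold higher in D351, list median 0.070). Of 13 epithelial genes only Upk1b did, at least 2.53-fold higher in D351, with a list median of -0.17 and a mean of 0.015. Among 26 neural and glial genes, the RNA-binding Celf4 was 4.96-fold higher in D16 and Nlgn3 at least 2.88-fold higher in D351 (median -0.11). Of 8 pluripotency and germ cell genes, 3 were higher in D16, namely Dnmt3l (at least 3.41-fold), Sall4 (3.01-fold) and Rif1 (2.54-fold), and 0 in D351, with a median of -0.22.

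Genes of body position and of imprinted loci went both ways. Of 28 Hox and positional genes, 5 were at least 2-fold higher in D351 and 7 in D16, with a median of -0.0094 and a mean of 0.29. Beside Sox11 and Hoxc8, Tbx19 was at least 3.12-fold higher in D351. Hoxb4 was 5.33-fold higher in D351 by its brightest probe set, while another read 8.9 in D16 and 11.6 in D351 and the remaining one read 15.8 in D16 and was dim in D351. Hoxa2 was 4.62-fold higher in D16, Foxj3 2.72-fold, Sox8 at least 2.69-fold and the orphan receptor gene Nr2f2 2.45-fold. The 13 imprinted genes had 2 higher in D351 and 3 in D16, with a median of -0.071 and a mean of 0.35. In the Dlk1-Meg3 domain, the maternally expressed non-coding RNAs Meg3 (10.8 in D16 and 75 in D351, at least 3.77-fold with the floor at 20.7) and Mirg were higher in D351. All 3 measured probe sets of each lay above 0. Those at 5.8 in D16 and 9.7 in D351 for Meg3, and at 6.9 and 8.9 for Mirg, were within the range of the negative controls and add little. Dlk1, the paternally expressed gene of that domain, was 2.54-fold higher in D16. Mcts2 (2.86-fold) and Peg12 (2.23-fold) were higher in D16 too.

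Among signalling lists, growth factors and receptor tyrosine kinases had 6 of 36 genes in each direction (median -0.099, mean 0.098). Pdgfd, dim in D16, reached 51.2 in D351, and the phosphatase gene Dusp15 stood at 9.9 in D16 and 66.6 in D351, at least 3.22-fold higher with the floor at 20.7. Fgf21 was at least 3.69-fold, Efna1 at least 3.38-fold and Efna5 2.27-fold higher in D16. Dusp22 was 2.35-fold higher in D16 but another probe set read 16 in D16 and 31.9 in D351. Of 16 axon guidance genes, Plxna1 (3.10-fold) and Plxnc1 (at least 2.19-fold) were higher in D351 and Flrt2 at least 4.05-fold higher in D16 (median -0.12). Of 28 cadherins, protocadherins and integrins, 5 were higher in D351, among them Gpc2 (at least 8.47-fold), Itga10 (at least 3.52-fold) and Itgb1bp1 (6.9 in D16 and 23.1 in D351), the latter 2 not past 2-fold with the floor at 20.7. Another 2, Alcam and Ctnnal1 (4.02-fold), were higher in D16, and the median was 0.16. Of 11 TGF-beta and BMP genes only the receptor gene Bmpr2 passed 2-fold, 2.59-fold higher in D16 (median 0.0090). Among 17 Notch and Hedgehog genes, Evc2 was 2.24-fold higher in D351, and Dlk1 and Dtx1 (14.4 in D16 and 6.7 in D351) in D16 (median -0.092, mean 0.0038). Of 14 cytokine and inflammation genes, Tnfrsf13c (6.6 in D16 and 18.2 in D351) and Il20rb (2.33-fold) were higher in D351, Il1rap (at least 2.70-fold) and Il17rd (2.42-fold) in D16 (median -0.28). This list stood apart towards D16 under 2 of the 8 settings, with a median of -0.58 for a floor at the 25th percentile and -0.69 over unmarked probe sets.

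No metabolic or housekeeping list stood apart. Of 16 cholesterol and fatty acid synthesis genes, Osbpl6 (3.83-fold) and the desaturase gene Fads2 (2.72-fold, 1160 and 427) were higher in D16 and 0 in D351, with a median of -0.29 at percentile 5.25. The 49 mitochondrial genes had 4 past 2-fold in each direction and a median of -0.21 (percentile 5.14). They did stand apart towards D16 under 2 of the 8 settings, with a median of -0.26 for a floor at the 75th percentile and -0.29 over unmarked probe sets. Mrpl38 (9.2 in D16 and 34.9 in D351), Tomm40 (3.75-fold), Idh3a (at least 2.88-fold) and Suclg2 (at least 2.20-fold) were higher in D351. Timmdc1 (at least 7.38-fold) and Mrps10 (4.08-fold) led towards D16. Of 12 glycolysis and hypoxia genes, Egln3 (at least 6.64-fold) and Pfkfb2 (2.05-fold) were higher in D351, against a median of -0.19 and a mean of 0.11. In the stress list of 38 genes, Prdx4 (2.15-fold) was higher in D351 and Hspa4l (2.79-fold) in D16, with 2 and 4 past 2-fold and a median of 0.0061. Of 37 ribosome and translation genes, Eef2kmt (4.10-fold) and Pes1 (2.78-fold) were higher in D351. Towards D16 lay Eif3c (3.53-fold), Eif6 (3.44-fold) and Rpl10l (at least 2.06-fold), and the median was 0.11. Of 6 control genes for RNA input, Gusb (8.5 in D16 and 17.9 in D351) was higher in D351 and Tbp (at least 2.12-fold) in D16, with a median of -0.36.

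The large gene families held many single differences. Of 97 zinc finger genes, 13 were higher in D351, led by Zfp407 (5.43-fold) and Zfp287 (5.32-fold), and 6 in D16, led by Zfp626 (at least 5.80-fold, but near 0 with the floor at the 25th percentile, where another of its probe sets, at 8.8 and 8.9, stands for it). Their median was 0.11, at percentile 94.5. Among 46 chromatin regulators, Arid5b (5.78-fold), Smarca1 (at least 3.47-fold) and Prmt2 (2.69-fold) were higher in D351 and Suv39h2 (at least 2.97-fold) and Phf10 (2.44-fold) in D16. The chromatin median was -0.00056 and the mean 0.057. Of 101 ubiquitin and proteasome genes, 11 were higher in D351, with Fbxo44 at least 6.11-fold, and 4 in D16, with Ube4b at 25.3 in D16 and 7.9 in D351 (median 0.050). Rnf157 and Rnf32 passed 2-fold by their brightest probe sets, towards D351 and D16, and both had another probe set past 2-fold the other way, which for Rnf157 read 26.3 in D16 and 10.2 in D351 and for Rnf32 was dim in D16 and at 16 in D351. Of 102 ion channels and solute carriers, 9 were higher in D351 and 10 in D16 (median -0.12). Cacna1c, the pore subunit of the L-type calcium channel, was at least 25.3-fold higher in D351. Slc35f1 was at least 17.9-fold higher in D16. The urea transporter gene Slc14a1 stood at 45.4 in D16 and 6.6 in D351, at least 2.19-fold higher in D16 with the floor at 20.7, but its second probe set read 14.3 in both clones.

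Genes of chromosome 10 were higher in D351 as a set, by chromosomes of assembly GRCm38.p6. Of its 205 measured genes, 31 were at least 2-fold higher in D351 and 9 in D16, and the median was 0.21, which 0 of 10000 matched random lists reached. Chromosome 7 went the other way, with 21 genes higher in D351 and 40 in D16 of 308 and a median of -0.17 at percentile 0.040. Chromosomes 18 (-0.20) and 4 (-0.14, 19 against 48 genes) also lay low, and chromosome 1 (0.097) lay high. Scaled to the hybridization controls, the medians of chromosomes 7, 18 and 4 were above 0 (0.44, 0.36 and 0.46), still at the low end of the random lists. In all 5 of 20 chromosomes stood apart, where 1 would by chance, and chromosome 4 no longer did under 3 of 8 alternative settings and chromosome 1 under 1. Another 5 stood apart under 1 setting each. Over unmarked probe sets these were chromosomes 2 (-0.17, percentile 0.16) and 12 (-0.18, percentile 1.5), at the 75th percentile floor 17 (-0.19, percentile 0.24) and 9 (0.13, percentile 98.7), and at the 25th percentile floor 11 (0.070, percentile 97.99).

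**Figure D4:**
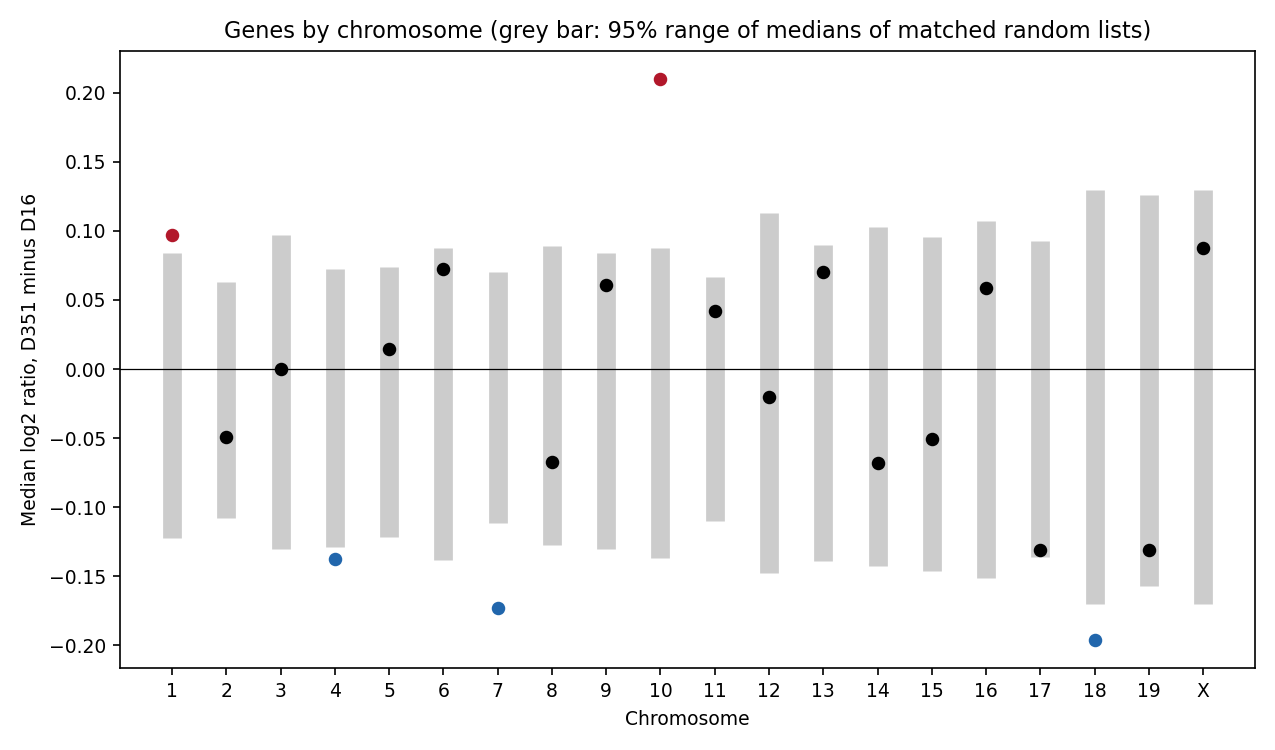
Median log2 ratio, D351 minus D16 (y axis), of the measured genes of each chromosome (x axis), with grey bars for the range that holds 95% of the medians of matched random lists. Chromosome 10 lies above its bar at 0.21 and chromosome 7 below at -0.17; scaled to the hybridization controls they were at 0.83 and 0.44.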

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

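Quantile normalization, lowess centring and equal medians left all 4 overall results close to their reported values. The cell cycle, fibroblast and small GTPase lists and chromosomes 7, 10 and 18 stood apart under all 8 settings fixed in advance that apply to lists. The cell cycle median ran from -0.66 to -0.44 and the fibroblast median from 1.37 to 1.96. Smooth muscle stood apart under 4, adipocyte under 5, and Wnt and interferon under 6. In the other direction, 11 calls appeared that the reported values do not make. The cardiac list stood apart with the pseudocount (0.70) and unmarked probe sets (1.49), the cytokine list with the 25th percentile floor (-0.58) and unmarked probe sets (-0.69), and the mitochondrial list with the 75th percentile floor (-0.26) and unmarked probe sets (-0.29). Chromosomes 2 and 12 did so with unmarked probe sets, 9 and 17 with the 75th percentile floor and 11 with the 25th. A floor at the 25th percentile raised the 2-fold counts to 1480 for D351 and 1668 for D16, by construction, since dim values then enter. It moved the matrix median to 0.35 and that of chromosome 18 to -0.32, and turned Rnf32 (1.46) and Zfp626 (0.016). A floor at the 75th percentile left 260 and 261 probe sets, a cell cycle median of -0.66 and -0.27 for chromosome 4. The pseudocount turned Rnf32 (0.88), and the 3-fold rule left 279 and 216 probe sets. Unmarked probe sets alone, fewer by construction, gave 429 and 409. Their smooth muscle median was 0.45, the fibroblast median 1.96 over 4 genes and that of chromosome 10 0.30. There the matrix median turned to -0.11 and Col6a4, dim in D351 by that probe set, to -0.85 or lower, and the cause is weighed among the other observations. Beyond these, the cause of each move was not tested.

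Chosen after the data had been seen, scaling to the hybridization controls gave 1836 and 241 probe sets, 88.4% of them higher in D351. It moved the medians of smooth muscle to 0.94, Wnt to 0.91, adipocyte to 1.06, matrix to 1.28, fibroblast to 2.24, interferon to 1.01, small GTPases to 0.93 and the cell cycle to -0.0061. Chromosomes 1, 10, 4, 7 and 18 came to 0.73, 0.83, 0.46, 0.44 and 0.36, and Rnf32 to 1.69. Under it smooth muscle no longer stood apart (percentile 96.5) and chromosome 9 did (98.7). The mural cell median moved by only -0.0077. Without the members shared with the fibroblast list, the matrix median was 0.45 over 26 genes, at percentile 99.85. The reverse left too few genes for a value. Of 173 named genes past 2-fold, 115 of the 146 still measured passed 2-fold at the 75th percentile floor, and 103 of the 107 with an unmarked probe set did so by it. With the pseudocount 147 of the 173 passed 2-fold and with scaling to the hybridization controls 139 did, with Rnf32 turned in both. Signal near the floor limits the rest: 5040 probe sets were dim in both clones.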

Other observations

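Several transcripts outside the lists stood out and were chosen after their values were seen. Pclaf, a PCNA-binding factor of replicating cells, was at least 22.9-fold higher in D351 (3.7 in D16 and 146 in D351), against the direction of the cell cycle list. The control probe set for murine Fas read 41.3 in D16 and 193 in D351. Control probe sets for repeat transcripts were brighter in D16, MUR_b2 by 3.75-fold, MURINE_b1 by 1.86-fold and MURINE_B2 by 1.73-fold. The hybridization controls were themselves a median of 1.59-fold brighter in D16, not far from MURINE_b1 and MURINE_B2. Mdm2 lies on chromosome 10, and of the 5 nearest measured genes on each side 7 of 10 were above 0 and 0 passed 2-fold, with a median of 0.38. Cand1 was 1.98-fold and Nup107 1.62-fold higher in D351, and Yeats4, next to Mdm2, had a log2 ratio of -0.17.

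The tests of RNA quality, of hybridization control scaling, of marked probe sets, of feeder cells and of neighbouring genes below were chosen after their results or related values had been seen. Cell cycle genes were lower in D351. Lowess centring left the list's median at -0.53 and a floor at the 75th percentile left it at -0.66 over 42 members, both below the random range, so neither an intensity-dependent scaling nor the noise of dim probe sets accounts for it. The mean log2 ratio of 3' to 5' probe sets of Gapdh and Actb, D351 minus D16, was -0.22, which argues against more degraded RNA in D351. Scaled to the hybridization controls the median was -0.0061, with 29 members above 0 and 29 below. It stayed at percentile 0 of the matched random lists, whose middle value was then 0.61. These are controls of the hybridization step, so they cannot tell whether levels of other genes were lower in the D16 cells. Why the controls were brighter in D16 was not tested, so the direction holds only relative to other genes. A hypothesis that remains is that D16 held more cycling cells at harvest, from the clone, from passage or from culture density, which was not tested here and which a measurement of DNA content in replicate cultures of both clones could test.

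Matrix genes were higher in D351. Lowess centring left the median at 0.68, which argues against a scaling trend as the whole cause. Over the 13 members with an unmarked probe set the median was -0.11, inside the random range, but by their brightest probe sets the same 13 had 0.23, also inside it, and 11 of them had the same value, so whether cross-hybridization of marked probe sets gave part of the shift stays open. All 8 measured fibroblast markers were higher in D351, which feeder cells carried over into that culture could give, but so could a more fibroblast-like clone. These cannot be told apart without an array of the feeder cells, and 6 of the 8 markers are matrix genes that mesenchymal clones also express.

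The medians of chromosomes 10 and 7 lay outside the random range. Of 3 equal parts by gene order, 2 lay outside the random range on each chromosome and 1 inside it (0.11 on chromosome 10 and -0.16 on chromosome 7), and without the most shifted part the medians were 0.16 over 136 genes and -0.17 over 205, both still outside, which argues against a few neighbouring genes as the whole cause. Without the members of the lists that stood apart, the medians were 0.18 over 189 genes and -0.17 over 293, both outside the random range. Chromosome 18 (median -0.20), which also stood apart under all 8 settings, was not examined by parts or quartiles. The lower quartile of chromosome 10 (-0.17, random range -0.64 to -0.34) and the upper quartile of chromosome 7 (0.22, random range 0.36 to 0.59) moved with the medians. These quartiles come from the same ratios by which the chromosomes were chosen, so they add little. A difference in copy number along the chromosome would also move them. This is a hypothesis: a gain from 2 to 3 copies in every D351 cell would give 0.58 against the 0.21 of chromosome 10, and a change from 3 to 2 or from 2 to 1 would give -0.58 or -1 against the -0.17 of chromosome 7, so it would have to be in part of the cells or compressed by the arrays, and chromosome counts or DNA sequencing, not analysed here, could test it.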
